A study of Homo sapiens with 2 samples.

How the data were processed

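Total RNA from Huh-7 cells, an established human hepatocellular carcinoma line, was measured on 2 expression arrays. One array held RNA of cells transfected with NC, the control as the labels name it, and the other RNA of cells transfected with siRNA against DEPDC1, both collected 72 h after transfection. Per the labels' protocols, RNA was extracted with TRIzol and biotinylated cRNA was prepared by the standard Affymetrix protocol. Per the submitters' processing notes, Affymetrix Expression Console and Transcriptome Analysis Console 3.0 were used. Neither their role nor the background correction, normalization or filtering is given in the sources used here. The sequence of the siRNA and the number of siRNAs are not given there either.

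The deposited table held 1 value per probe set and array for 33297 probe sets. No label states the unit. The deposited values ran from 1.39 to 12.7 with medians of 4.67 (NC) and 4.64 (siRNA), so they were taken as log2 expression. The quartiles were 3.21 and 6.48 in the NC array and 3.19 and 6.51 in the siRNA array. The sorted columns differed by at most 0.0997 at any rank, so the deposited values were taken as already normalized between the arrays, and they were used without further scaling. Pearson's r between the arrays was 0.989 across probe sets, which are not independent replicates. The slope of the difference on the mean was -0.0057 over detected genes. Background signal compresses differences of dim genes, so their folds can be understated. Scanner intensities, detection calls and control probe sets were not analysed here, so RNA quality was not checked. The number of arrays limits the precision of every value.

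Probe sets were named through GEO's platform annotation. It gave 1 gene for 19460 probe sets, several for 1754 and listed no gene for 12083. Symbols were updated through Entrez identifiers against the RefSeq gene table of GRCh38.p14, which matched 19429 of the 19460. The build behind the array annotation is not given in the sources used here, so no gene coordinates are printed. Probe sets of several genes or of none stayed out of the gene results. Of the 18417 genes left, 769 had more than 1 probe set, and the probe set with the highest mean of both arrays was used. A gene counted as detected when the higher of its 2 values reached the median of all probe sets over both arrays, 4.66, which left 11352 genes. Control probe sets are not marked in either table and could not be left out of that median as planned. The threshold is a convention and not a measured background. Where a value lay under it, the fold is given as a bound against the threshold ("at least").

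Each difference is the siRNA value minus the NC value on the log2 scale. With 1 array per group there is no replicate spread, so no test was run and no p-value is given. Genes were counted at a fold of at least 2 by their measured values, so a gene counted as 2-fold different can have a bound under 2. As a gauge of measurement noise alone, the differences of different probe sets of the same gene were compared. Over 444 genes with 2 or more detected probe sets, their median range was 0.0866 and the 90th percentile 0.413 on the log2 scale. Some of these probe sets may share probes, so the gauge can be too small.

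Gene lists were fixed before the data were examined: 7 lists chosen for the question (mitosis, S phase and DNA replication, p53 targets, NF-kB targets, chemokines and cytokines, angiogenesis, invasion and EMT), 26 further lists of pathways and hepatocyte functions, and 7 lists of markers of other cell types. For each list with at least 5 detected genes, the median difference was placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. A median below the 2.5th or above the 97.5th percentile was called apart. This describes these 2 arrays and is no test of the siRNA: genes that vary together between any pair of cultures also give medians outside that range. Lists overlap in some genes. The genes named in the text were also chosen by a rule fixed before the data were examined: DEPDC1, the 12 genes with the largest difference in each direction among detected genes with an official symbol, up to 4 detected members with the largest absolute difference from each list, and CCL20, CCR6, TNFAIP3, ZNF224 and DEPDC1B. Any other gene is named as chosen after its value was seen.

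On simulated data with the levels of this comparison and a noise SD of 0.15 per array, 192 of 200 genes changed by 1.5 on the log2 scale were recovered among 11315 detected genes, and 0 unchanged genes passed the threshold. Of 200 simulated unchanged lists 5 were called apart, and of 50 lists shifted by 0.3 all 50 were. The simulated noise was independent between genes and was not fitted to these arrays, whose differences had an SD of 0.397 over detected genes. The simulation thus checks the procedure only and gives no rate of false calls for the counts or lists below. The alternatives covered the filter on dim probe sets, the probe set per gene, quantile normalization, median centring, removal of a loess trend (span 0.3), a floor at the 25th percentile, the fold threshold, a count over genes with 2 or more agreeing probe sets and the mean in place of the median. A detection threshold from gene-listed probe sets and a floor at the detection threshold were added after seeing the data. The analysis used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.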

Results

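Gene expression was profiled in Huh-7 hepatocellular carcinoma cells 72 h after transfection with DEPDC1 siRNA or with the control NC. DEPDC1 encodes a DEP domain protein. The comparison asks which transcripts differ when DEPDC1 is depleted in this line. Each group had 1 array, labelled as biological replicate 1, so no difference below has a replicate check and none carries a p-value. Of 18417 genes measured by a probe set of their own, 11352 were detected.

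The targeted transcript was lower in the siRNA array. DEPDC1 (probe set 7916898, Entrez gene 55635) had a log2 expression of 7.82 in the NC array and 5.15 in the siRNA array, a log2 difference of -2.67 or 6.37-fold lower. It ranked among the 12 largest decreases. Its paralog DEPDC1B was 1.93-fold lower (7.73 against 6.78, difference -0.95). Among the 17 detected DEP domain and GATOR genes, DEPDC1 was the 1 member at least 2-fold lower and none was at least 2-fold higher. SEC13 differed by 0.51 and NPRL3 by 0.44, and the list median of 0.00 lay at the 50.7th percentile of matched random lists. By its mean of -0.16 the list was apart, at the 2.25th percentile. That mean includes DEPDC1, the siRNA target, at -2.67, so it is no sign of a shift of the other members. ZNF224, a zinc finger repressor known to bind DEPDC1, differed by 0.22 (5.14 against 5.36).

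In total 220 genes were at least 2-fold higher and 98 at least 2-fold lower in the siRNA array, which is 1.94% and 0.863% of the detected genes. At a threshold of 4-fold, 30 were higher and 6 lower. ANXA1, the phospholipid-binding protein annexin A1, had the largest difference: 4.24 in the NC array, under the detection threshold, and 10.07 in the siRNA array, at least 42.4-fold higher. SLC1A3, a glutamate transporter, was 10.4-fold higher. EREG, the EGF receptor ligand epiregulin, was 7.55-fold higher. GPRC5A, a retinoic acid-inducible receptor, was 7.22-fold higher. EDN1, the vasoactive peptide endothelin 1, was 5.62-fold higher. SCGN, a calcium-binding protein, was 5.14-fold higher, and LUM, the matrix proteoglycan lumican, 4.95-fold higher (7.64 against 9.95). Of the other genes in the upper 12, COL12A1, a fibril-associated collagen, was at least 6.70-fold higher. KCND2, a potassium channel, was at least 3.81-fold higher. GPX8 was at least 3.77-fold higher, EMP1 at least 2.40-fold and IGSF10 at least 1.32-fold, since their NC values lay under the threshold.

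Besides DEPDC1, the genes with the largest decreases included secreted liver proteins, metabolic enzymes and a Polycomb protein. SCML2, the Polycomb protein, was 6.57-fold lower (7.64 against 4.92). GPX2, a glutathione peroxidase, was 4.60-fold lower, and HSD17B2, a steroid dehydrogenase, 4.11-fold lower. KNG1 (kininogen) was 4.03-fold lower and AFP (alpha-fetoprotein) 3.92-fold lower, from 10.89 to 8.92. ORM2 and ORM1, the acute-phase orosomucoids, were 3.57-fold and 3.43-fold lower. These 2 genes are near-identical copies whose probe sets can share signal. ANKRD46 was 4.39-fold lower, SLC38A3, a glutamine transporter, 3.81-fold, MGAT4A, a glycosyltransferase, 3.67-fold, and LGALS14, a galectin, 3.62-fold. Among the genes at least 2-fold different, 64 of the 220 higher genes lay under the detection threshold in the NC array and 12 of the 98 lower genes lay under it in the siRNA array. With values under the threshold raised to it, a setting chosen after seeing the data, 183 genes were at least 2-fold higher and 91 lower.

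**Figure D1:**
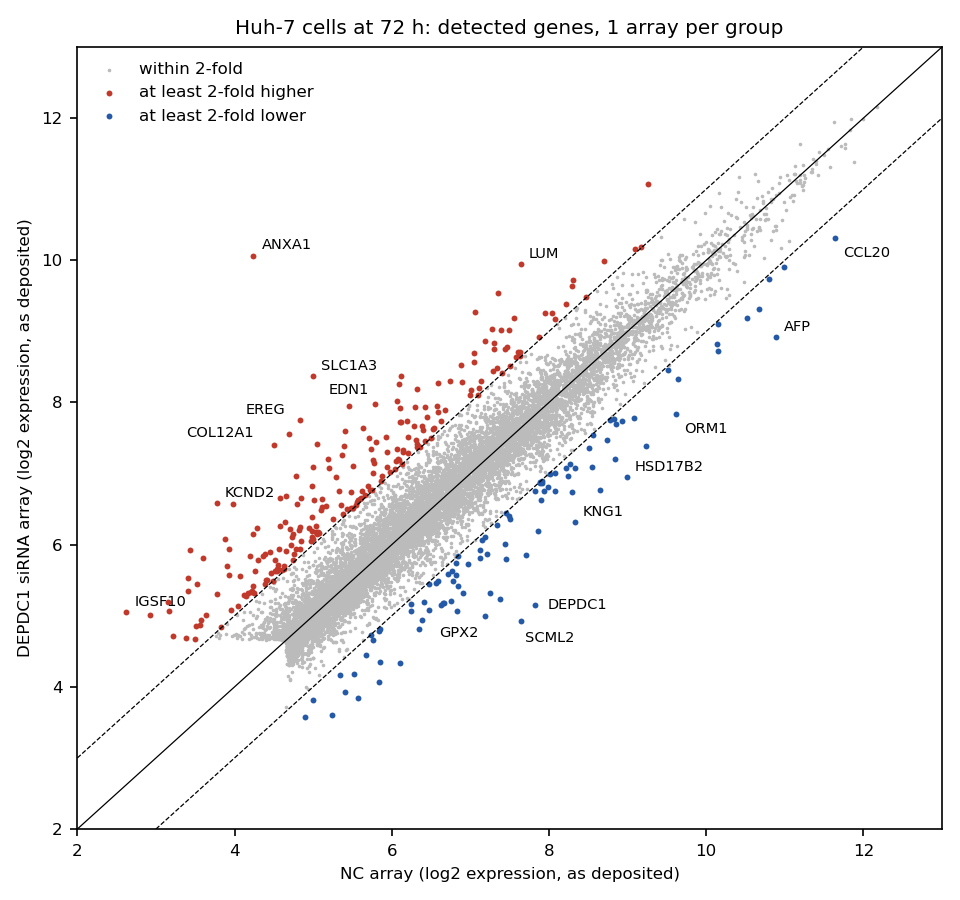
Log2 expression of each detected gene in the NC array (x axis) and in the DEPDC1 siRNA array (y axis), 1 array per group; the solid line marks equality, the dashed lines a 2-fold difference, and red and blue points the 220 genes at least 2-fold higher and the 98 at least 2-fold lower. ANXA1 lies farthest above the line, at 4.24 and 10.07, and DEPDC1 lies below it at 7.82 and 5.15.

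Of the 40 gene lists, 35 had enough detected genes for a median. The medians of 16 lay outside the central 95% of matched random lists, 10 lower and 6 higher, against 1.75 lists that random gene choice would give. Of these 16, 11 stayed outside that range under every alternative that was run.

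Transcripts of hepatocyte products were lower in the siRNA array. Of 24 detected secreted hepatocyte proteins, 9 were at least 2-fold lower as measured, 1 was at least 2-fold higher and 14 lay between. AHSG, named after its value was seen, lay under the threshold in the siRNA array and was at least 1.82-fold lower. The list median of -0.52 was below all 10000 random lists. ORM2, ORM1, SERPINA1 (alpha-1-antitrypsin, 3.18-fold lower) and APOC3 (apolipoprotein C-III, 2.73-fold lower) differed most. The 2 probe sets of APOC3 gave -1.45 and -1.46. TTR (transthyretin), named after its value was seen, was the 1 member at least 2-fold higher, with 8.31 against 9.72. In the complement and coagulation list, 4 of 19 detected genes were at least 2-fold lower and none was higher by that much. Its median was -0.36, below all random lists. KNG1 was followed by SERPINF2 (alpha-2-antiplasmin, 2.87-fold lower), CPB2 (a carboxypeptidase of fibrinolysis, at least 2.28-fold lower) and C3, the central complement component (2.68-fold lower). In the same array, the 6 detected fibroblast and stellate cell markers had a median of 0.58, at the 99.9th percentile of random lists. LUM was 4.95-fold, FBN1 4.55-fold and COL1A2 2.10-fold higher. PDGFRA, COL1A1 and COL3A1 differed by 0.09, 0.06 and -0.04, COL1A1 and COL3A1 being named after their values were seen. Over all 14 markers without the filter the median was 0.08, at the 91.7th percentile.

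Hepatocyte transcription factors were lower as a list, with a median of -0.38 over 19 detected genes, below all random lists. Only CEBPA, which drives hepatocyte differentiation, passed 2-fold (2.49-fold lower, 8.07 against 6.76). ONECUT1 differed by -0.95, GATA4 by -0.85 and HNF4G by -0.72. These decreases, too, stood beside a higher median of the detected fibroblast and stellate cell markers (0.58), which was 0.08 over all 14 without the filter. Hepatocyte enzymes and cytochromes P450 had 3 of 15 detected genes at least 2-fold lower and 1 higher, with a median of -0.16 at the 3.58th percentile, inside the random range. By its mean of -0.21 this list was apart, at the 0.46th percentile. BAAT, which conjugates bile acids, was at least 1.88-fold lower, UGT2B4, a glucuronosyltransferase, 2.79-fold lower and CYP2B6 2.01-fold lower. PCK2, mitochondrial phosphoenolpyruvate carboxykinase, was 2.90-fold higher. Fetal liver and hepatocellular carcinoma markers went both ways. AFP was lower, TSPAN8, a tetraspanin, at least 4.01-fold higher, PROM1, the surface marker CD133, 2.25-fold higher, and CD24 differed by -0.54. Their median of 0.11 over 23 genes lay at the 94.1th percentile.

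**Figure D2:**
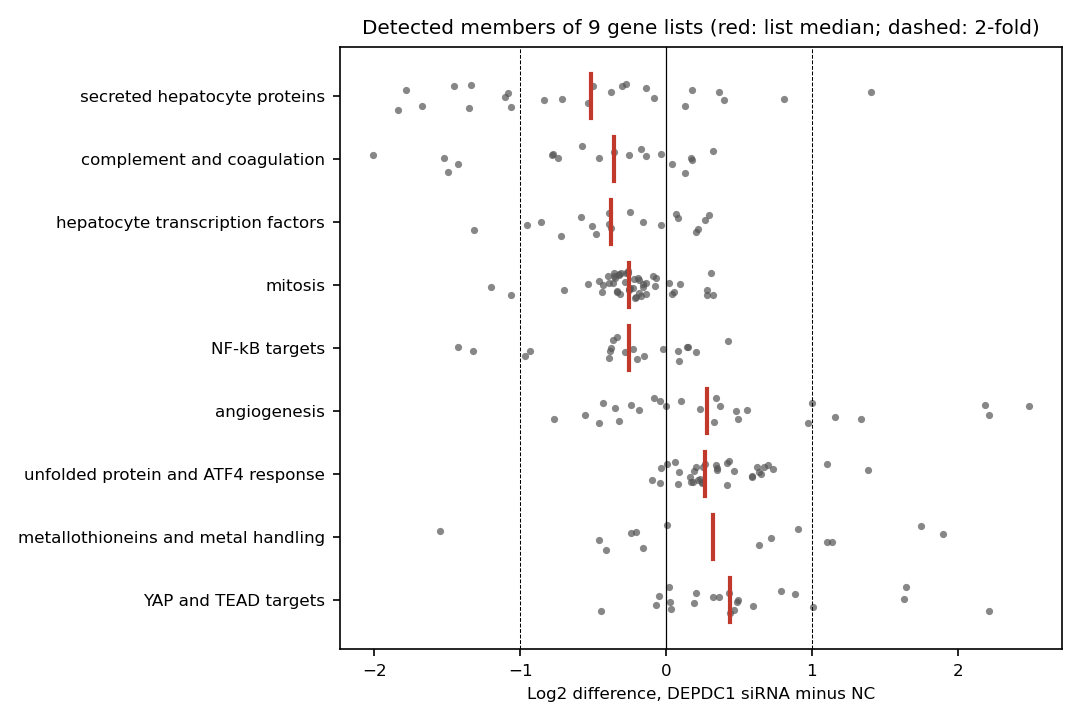
Log2 difference (siRNA minus NC, x axis) of every detected member of 9 gene lists, 1 point per gene, with the list median in red and dashed lines at a 2-fold difference; vertical spread within a list only separates the points. The 24 secreted hepatocyte protein genes have a median of -0.52 and the 22 YAP and TEAD target genes one of 0.44, while the 49 mitosis genes lie mostly within 2-fold with a median of -0.25.

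Genes of cell division were slightly lower. Among 49 detected mitosis genes, 41 had a lower value in the siRNA array and 8 a higher value. Their median of -0.25 was below all random lists. At least 2-fold lower were NUSAP1, a spindle protein (2.29-fold), and MKI67, the proliferation marker Ki-67 (2.09-fold). KIF11, a mitotic kinesin, differed by -0.70 and NCAPG, a condensin subunit, by -0.53. Among 44 S phase and DNA replication genes, 31 were lower and 13 higher, none by 2-fold. Their median of -0.10 lay at the 0.77th percentile. CCNE2 (cyclin E2) differed by -0.82, MCM4 by -0.58, DNA2 by -0.56 and GINS2 by 0.52. Replication-dependent histones had a median of -0.01 over 11 genes (45.3th percentile), with H2BC12 2.15-fold higher and H2BC21, H2AC25 and H2AC6 at 0.49, -0.36 and 0.34.

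p53 targets did not stand apart, with a median of 0.07 over 25 genes at the 79.9th percentile. Over the 12 members whose level reached the 75th percentile of all probe sets, the sign was the opposite, with a median of -0.26 at the 0.48th percentile. PLK2 was 3.65-fold higher and ZMAT3 2.34-fold lower, while TP53INP1 differed by -0.70 and POLH by -0.63. Apoptosis regulators had a median of 0.09 over 27 genes (80.7th percentile). BCL2L11, which encodes the pro-apoptotic protein BIM, was 2.99-fold lower. BID differed by -0.72, CASP8 by 0.62 and PMAIP1 by 0.46. Senescence-associated genes had a median of 0.17 over 14 genes (94.7th percentile), and the 3 members at least 2-fold higher were EREG, TIMP1 and TIMP2. IGFBP3 differed by 0.60. The mean of this list was 0.41, at the 99.7th percentile.

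CCL20 and its receptor CCR6 were both lower. CCL20, a chemokine, had a log2 expression of 11.64 in the NC array and 10.31 in the siRNA array, a difference of -1.32. CCR6 had 5.24 in the NC array and 3.61, under the detection threshold, in the siRNA array. Its fold is thus a bound against the threshold, and that bound was under 2-fold. NF-kB targets were lower as a list, with 14 of 20 detected genes lower, 6 higher and a median of -0.25 at the 0.01th percentile. C3 and CCL20 were the 2 members at least 2-fold lower. TNFAIP3, which encodes the NF-kB inhibitor A20, was 1.96-fold lower (5.63 against 4.66), and REL, an NF-kB subunit, 1.90-fold lower. Chemokines, cytokines and their receptors had a median of -0.27 over 17 genes (0.11th percentile). By measured values, CCL20 and CCR6 were at least 2-fold lower and CXCL5 and CXCR4 at least 2-fold higher. The bounds of CCR6 and CXCR4 against the threshold were under 2-fold. CXCL5 was 3.13-fold higher and CXCR4 at least 1.16-fold higher. This list was not apart by its mean of -0.088, nor over all 32 members on the array without the filter (median -0.011, 56.5th percentile). It shares 4 detected genes with the NF-kB targets, CXCL1, CXCL2, CXCL8 and CCL20. Interferon-stimulated genes had a median of -0.11 over 14 detected genes, inside the random range. MX2 was at least 1.87-fold higher, IFIT5 at least 1.25-fold lower and OAS1 at least 1.13-fold lower, while IRF9 differed by 0.39.

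The angiogenesis list was higher, with a median of 0.28 over 26 genes at the 99.99th percentile, although 11 of the 26 were lower. The members at least 2-fold higher were EDN1, CCN1 (a matricellular protein, 4.63-fold), NRP2 (a semaphorin and VEGF co-receptor, 4.57-fold), FLT1 (a VEGF receptor, at least 1.15-fold against the threshold) and EFNB2, the last named after its value was seen (2.23-fold). The 2 probe sets of NRP2 gave 2.19 and 2.03. With a detection threshold taken from gene-listed probe sets, chosen after seeing the data, 23 genes were left and the median was 0.10, at the 86.2th percentile. Invasion and EMT genes had a median of 0.10 over 28 genes (93.5th percentile), inside the random range. TIMP1 and TIMP2, inhibitors of matrix metalloproteinases, were 2.46-fold and 2.06-fold higher, MMP14 differed by 0.89, and SNAI2, an EMT transcription factor, was 2.25-fold lower.

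Targets of YAP and TEAD were higher, 19 of 22 detected genes having a higher value and 4 being at least 2-fold higher. The median of 0.44 was above all random lists. These 4 were CCN1, MYOF (3.13-fold), TGFB2 (3.10-fold) and CCN2 (2.01-fold). Of the 6 detected fibroblast and stellate cell markers, LUM, FBN1 and COL1A2 were at least 2-fold higher in the same array, while PDGFRA, COL1A1 and COL3A1 differed by 0.09, 0.06 and -0.04 (list median 0.58). COL1A1 and COL3A1 were named after their values were seen. Immediate early genes and MAPK feedback regulators had 22 of 30 genes higher, none by 2-fold, and a median of 0.21 at the 99.6th percentile. PHLDA1 differed by 0.84, DUSP10 by 0.81, KLF6 by 0.71 and MYC by 0.71. Over the 16 members at or above the 75th percentile of all probe sets, that list was inside the random range (93.98th percentile). TGF-beta targets had a median of 0.05 over 22 genes (68.9th percentile). Besides CCN2, ID2 differed by -0.86, JUNB by -0.70 and TGFB1 by 0.70. Wnt targets had a median of -0.0012 over 15 genes (43.4th percentile), with BMP4 2.01-fold higher, CCND1 at -0.54 and LGR5 at 0.42. Mean and median differed in sign for TGF-beta targets (mean -0.0055) and Wnt targets (mean 0.12), as they did for p53 targets (-0.048), interferon-stimulated genes (0.020), replication-dependent histones (0.12), fatty acid oxidation genes (-0.031) and oxidative phosphorylation genes (0.0037), none of them apart by either.

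Genes of the unfolded protein and ATF4 response were higher, 32 of 35 having a higher value, with a median of 0.27 above all random lists. VLDLR was 2.62-fold higher and SLC7A11, a cystine transporter, 2.15-fold higher. ASNS, asparagine synthetase, differed by 0.73 and TRIB3 by 0.70. Metallothioneins and metal handling genes had a median of 0.32 over 14 genes (99.9th percentile). MT1M was 3.73-fold, MT1G 3.36-fold and MT1E 2.20-fold higher, MT1F, named after its value was seen, 2.15-fold higher, and SLC30A10, a manganese exporter, 2.93-fold lower. Metallothionein genes are close paralogs whose probe sets can share signal. NRF2 targets were lower, with a median of -0.16 over 23 genes (0.98th percentile). GPX2 and GCLM (2.03-fold lower) were at least 2-fold lower, SLC7A11 was higher, and ABCC3 differed by 0.59. Cytosolic heat shock genes had a median of 0.08 over 18 genes (84.0th percentile), CHORDC1 differing by -0.54, HSPB1 by 0.48, FKBP4 by 0.39 and HSPA4 by -0.35.

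Most lists of energy and lipid metabolism did not stand apart. Hypoxia and glycolysis genes had a median of -0.10 over 31 genes (5.34th percentile), with ADM at 0.97, PDK1 at -0.86, ALDOC at -0.78 and PFKFB3 at -0.77. Over the 23 members at or above the 75th percentile of all probe sets, the median was -0.23, at the 0.06th percentile, and thus apart. Cholesterol synthesis genes had a median of -0.03 over 20 genes (37.1th percentile), with STARD4 at -0.67, SC5D at -0.47, ACLY at 0.41 and IDI1 at -0.41. Fatty acid and lipid synthesis genes had a median of -0.13 over 24 genes (2.59th percentile), next to the limit, and were apart without the filter (-0.17, 0.47th percentile) and by their mean (-0.18, 0.53th percentile). APOB, the structural protein of very low density lipoprotein, was 2.55-fold lower and GPAM 2.05-fold lower, with PLIN2 at -0.94 and DGAT2 at -0.78. Fatty acid oxidation and PPARA targets had a median of 0.06 over 18 genes (64.2th percentile), although CPT1A, the carnitine palmitoyltransferase of the liver, was 2.10-fold lower. HADH differed by -0.84, ETFDH by 0.57 and ACADVL by 0.53. Oxidative phosphorylation genes had a median of -0.0017 over 32 genes (44.9th percentile), with NDUFA8 at 0.46, NDUFS1 at -0.46, SDHC at 0.39 and COX7B at -0.38.

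Ribosomal protein genes were slightly lower, 29 of 33 having a lower value, none by 2-fold, with a median of -0.14 at the 1.52th percentile. RPS23 differed by -0.70, RPL22 by -0.65, RPL10A by -0.39 and RPL32 by -0.36. Autophagy genes had a median of 0.11 over 34 genes (93.6th percentile), BECN1 and ATG4A each differing by 0.65, CTSD by 0.55 and LAMP1 by 0.52. Genes of the small RNA pathway had a median of -0.24 over 13 genes (0.49th percentile). TNRC6C differed by -0.48, DROSHA by 0.46, DGCR8 by -0.32 and DICER1 by -0.30. By its mean, and over the 9 members at or above the 75th percentile of all probe sets, this list was inside the random range (2.84th and 2.69th percentile).

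Markers of other cell types were mostly under the detection threshold. Of 14 fibroblast and stellate cell markers 6 were detected, with a median of 0.58 at the 99.9th percentile. LUM, FBN1 (fibrillin 1, 4.55-fold) and COL1A2 (2.10-fold) were at least 2-fold higher, and PDGFRA differed by 0.09. Over all 14 markers without the filter the median was 0.08, at the 91.7th percentile. Macrophage markers had a median of -0.03 over 6 detected genes (42.3th percentile), although the mean was 0.14, with LYZ 2.30-fold higher, CD14 at 0.27, C1QB at least 1.21-fold lower and C1QC at least 1.07-fold lower. The remaining lists had fewer than 5 detected genes. CD3G, the detected lymphocyte marker, differed by -0.16. The endothelial markers EGFL7 and CLDN5 differed by -0.30 and -0.19. Of 4 detected neuronal markers, MAP2 was at least 2.98-fold higher and SYP at least 1.06-fold higher, while SYT1 differed by 0.98 and SNAP25 by -0.52. Of 4 squamous and basal epithelial markers, DSC3 was at least 1.17-fold higher and KRT13 at least 1.22-fold lower, while SFN differed by 0.52 and KRT14 by -0.31. Of 4 kidney epithelial markers, CDH6 was 2.22-fold higher, PAX8 at least 1.05-fold lower, and LHX1 differed by -0.21 and SIX2 by -0.17.

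**Figure D3:**
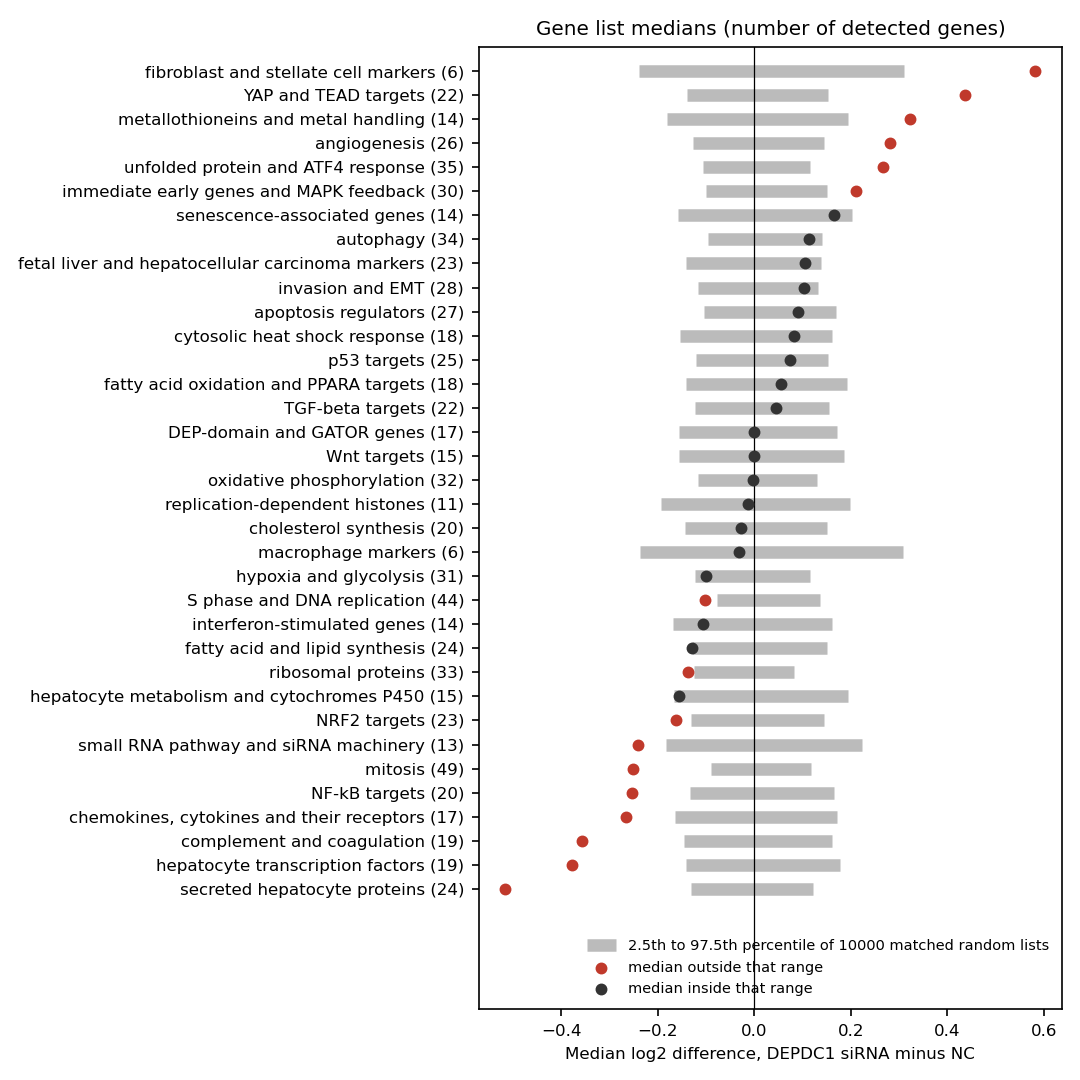
Median log2 difference (siRNA minus NC, x axis) of each gene list with at least 5 detected genes, the number of detected genes in parentheses; grey bars span the central 95% of medians of 10000 random lists matched on size and expression, and red points mark the 16 medians outside that range. The secreted hepatocyte proteins have the lowest median, -0.52, and the 6 detected fibroblast and stellate cell markers the highest, 0.58.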

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

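Probe sets that the annotation lists with no gene, or with several, stood outside the gene comparison, and some had values above those of the control array. Of the 4273 detected probe sets with no listed gene, 27 were at least 2-fold higher in the siRNA array and 68 at least 2-fold lower. The largest increase was that of probe set 8095744 (4.31, under the detection threshold, against 7.58), and the largest decrease that of probe set 8100853 (7.99 against 4.63, under the threshold). Of the 1024 detected probe sets that name several genes, 7 were at least 2-fold higher and 7 at least 2-fold lower.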

How the results depend on the processing

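DEPDC1 differed by -2.66 to -2.68 under every alternative run on it. It has 1 probe set and passed every filter, so only quantile normalization (-2.66) and loess removal (-2.68) changed its value. The other settings are thus no check on it. The count of genes at least 2-fold higher, 220, was 137 at a detection threshold at the 75th percentile, which leaves 5757 genes. At a threshold of 1.5-fold, 685 genes were higher and 424 lower, and at 3-fold 67 and 20. Of the 444 genes with 2 or more detected probe sets, 5 were higher and 5 lower by the probe set reported. When all their probe sets had to agree, the counts were 1 and 2. The excess of higher genes was not seen among them, but counts this small can neither show nor refute it. The filters, probe set rules, scalings and floors otherwise gave 183 to 230 genes higher and 76 to 101 lower. Quantile normalization, centring and loess removal moved the median difference of detected genes by at most 0.021. Of the lists chosen for the question, the chemokine list was no longer apart without the filter (-0.011) or by its mean (-0.088), and the angiogenesis list with a threshold from gene-listed probe sets (0.10), a setting chosen after seeing the data. The p53 targets changed sign and became apart at the 75th percentile threshold (-0.26). The cause was not tested for these lists. Their other 73 values kept their side of the limits. Of the values of the further lists, 290 kept their side, 4 were no longer apart and 8 became apart. Of the values of named genes, 1540 moved by less than the probe set gauge and 23 by more, with no change of sign. Most named genes have 1 probe set, so the filters and probe set rules could not move their values. No paired analysis was possible because each group has 1 array, and no array could be left out. Signal over background is unknown, which limits the folds of dim genes.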

Other observations

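The gene groups of this paragraph, the matrix genes and the zinc finger genes were chosen after their values were seen. So were the tests of an intensity trend, of dilution, of fibroblasts and of dim matrix genes, and the bootstrap comparison that decides the copy-number test. Of ligands of the EGF receptor, EREG (7.55-fold higher) and HBEGF (at least 2.80-fold higher, with 4.23, under the detection threshold, against 6.15) were the detected members with a probe set of their own. Class 3 semaphorins, secreted guidance proteins, were higher in 4 of the 5 detected members: SEMA3A 3.50-fold, SEMA3C at least 3.16-fold, SEMA3E 3.09-fold and SEMA3D 2.24-fold, with SEMA3F at -0.25. NRP2, a semaphorin co-receptor, was also higher, while NRP1 differed by 0.34. Which of these semaphorins act through either was not measured. Of 12 detected beta protocadherins, clustered neuronal adhesion genes, 5 were at least 2-fold higher, led by PCDHB8 (2.60-fold) and PCDHB5 (2.59-fold), and PCDHB18P, under the threshold in the siRNA array, was the 1 member with a lower value. These genes are similar in sequence, and their probe sets can share signal. In a scan of 139 families by symbol, 22 had medians outside the central 95% of matched random lists, against 6.95 that random gene choice would give. Members of a family can vary together, so this is no test. The 22 went both ways. Among the lower ones were the families with the symbols ANXA (-0.26, although ANXA1 was higher), CNOT (-0.25), FBXL (-0.23) and RAD (-0.20). Among the higher ones, the beta protocadherins had a median of 0.93 and the 15 intraflagellar transport genes one of 0.34, with IFT52 the farthest at 0.86. The GABA-A receptor subunits GABRA4 and GABRB1 lay under the threshold in the NC array (3.17 and 3.90) and above it in the siRNA array (5.07 and 5.70). GABRR1 and GABRA2 differed by 0.96 and 0.90, GABRE by -0.82 and GABRR2 by -0.052.

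Secreted hepatocyte proteins were lower, with a median of -0.52. An intensity trend between the arrays is argued against, since the median was still -0.49 after a loess trend was removed. Dilution of Huh-7 RNA by other cells would lower all members alike. But 12.5% of the 24 detected members were higher by more than the SD of the differences of all detected genes, 0.40. They were TTR at 1.41, HPX at 0.81 and, at that limit, APOA2 at 0.40. Dilution alone does not account for these members. For the list as a whole that share cannot decide. Of all detected genes, 6.03% were at least 1.5-fold higher, so single genes differed upward apart from any shift of the list. Dilution thus stays open for the list. In the same array, the 6 detected fibroblast and stellate cell markers had a median of 0.58, at the 99.9th percentile of random lists. LUM differed by 2.31, FBN1 by 2.19 and COL1A2 by 1.07, but PDGFRA, COL1A1 and COL3A1 by 0.09, 0.06 and -0.04. Over all 14 markers without the filter the median was 0.08, at the 91.7th percentile, inside the random range. A difference between the cultures or arrays that is unrelated to DEPDC1 cannot be told apart from the transfection, since the number of arrays per group is 1, and an effect of the siRNA on other transcripts than DEPDC1 was not tested.

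Of 38 detected collagen, laminin and fibrillin genes, 6 were at least 2-fold higher as measured (COL12A1, FBN1, FBN2, LAMA4, COL4A6 and COL1A2), 4 of them with values under the threshold raised to it (LAMA4 then at least 1.61-fold and COL4A6 at least 1.99-fold), and 0 were lower by that much. The group as a whole was not shifted alike: 19 members were higher, 18 lower and 1 equal, and the 30 collagen genes had a median of -0.048, at the 19.9th percentile of random lists. Fibroblasts or stellate cells in the siRNA culture are argued against as the whole source: 3 of their 14 markers were at least 2-fold higher, and of the genes abundant in such cells COL1A1 had 5.81 and 5.87 in the NC and siRNA arrays and COL3A1 5.01 and 4.97, differing by at most 0.059, with COL6A3 (3.76 and 3.70) and DCN (2.33 and 2.49) under the detection threshold in both. Noise of dim probe sets stays open for COL12A1, LAMA4 and COL4A6, whose NC values lay under the detection threshold, and for COL1A2 (5.43 and 6.50). FBN1 (5.79 and 7.98 in the NC and siRNA arrays) and FBN2 (6.07 and 8.02) lay above that threshold in both. They were not dim by their mean of both arrays, which reached the stricter threshold of 6.49 in 2 of the 6 genes. Dim genes as a class did not differ more, with an SD of the differences of 0.399 in the dimmest and 0.368 in the brightest of 8 bins. But the 6 were picked as the highest of their group, and no replicate gives the error of a single probe set. Noise of a single probe set thus stays open for FBN1 and FBN2 too. A change in the state of the Huh-7 cells also stays open, as a hypothesis that 1 array per group cannot test.

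Zinc finger (ZNF) genes were higher as a family: 234 of 339 detected had a higher value, 14 were at least 2-fold higher as measured and 7 with values under the threshold raised to it, 0 were lower by that much, and the median was 0.17. The shift lay on chromosome 19, where 163 ZNF genes had a median of 0.29, while the 176 elsewhere had 0.04, at the 93.5th percentile of random lists. A copy-number difference of that chromosome would raise neighbouring genes alike, but the 52 non-ZNF genes next to a ZNF gene there had a median of 0.088 (bootstrap 95% interval -0.08 to 0.12), below that of the ZNF genes, which argues against it as the whole cause. A part stays open, since the neighbours lay at the 96.7th percentile and the 650 other non-ZNF genes of the chromosome, with a median of 0.06, at the 99.99th. Noise of dim probe sets is also argued against, since the 77 ZNF genes at or above the 75th percentile of all probe sets had a median of 0.21, at the 99.96th percentile, while shared signal between these similar genes and a common regulation of the clusters were not tested.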
